A study of Pimephales promelas with 12 samples.

How the data were processed

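Liver RNA of 12 female fathead minnows (Pimephales promelas), 3 in each of 4 dose groups, was hybridized to 12 one-colour (Cy3) Agilent custom arrays. The fish had been held for 96 h in flowing water with 0, 1, 10 or 100 ng/L diethylstilbestrol (DES), a synthetic estrogen. Labelled cRNA was made with a Quick Amp kit, per the labels' protocols. Each array held 15208 probes of 60 bases and 536 control spots. The control spots were left out.

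The scanner files were deposited as spot intensity values, and per the file headers they came from Agilent Feature Extraction version 10.7.3.1. The submitters' processing notes name version 9.5 instead. The processed intensity is background-subtracted and spatially detrended by that program, per the file headers, and is not normalized between arrays. The authors' deposited value table holds log2 values. Set against the scanner values, it matched the log2 median spot intensity after a cyclic loess within each dose group, with a root mean square difference of 0.035 to 0.0827 per array. Against the same loess over all 12 arrays the difference was 0.0794 to 0.742. The table's array medians ran from 5.91 to 6.47. Its scale is therefore log2, its direction is that of the signal, and whether any further centring was applied is not stated. The table served only as an alternative, because group means normalized apart cannot be set against each other safely. No per-sample column of the table was left unmapped.

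The series' design text states that the 12 exposure arrays were normalized with Fastlo, the fast form of cyclic loess. The log2 processed intensity was therefore normalized here by limma's fast cyclic loess over the 12 arrays (span 0.7, 3 iterations). Spots that the files mark as non-uniform or as population outliers (0 to 19 per array) were then set to missing, and saturated spots were kept. Probes well above background on 3 or more of the 12 arrays entered the tests, which left 12233. All 12 arrays were fitted with group means and no block in limma 3.58.1 (R 4.3.3) using lmFit and eBayes. Tests were two-sided, with Benjamini-Hochberg adjustment over the 12233 probes and a threshold of 0.05. The residual standard deviation had a median of 0.682 on the log2 scale, and the standard error of a difference of 3 fish against 3 had a median of 0.557. The dose trend is the slope of the group means over dose ranks. The number of arrays limits the precision of every value.

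The files give every probe an ID and a contig or sequence name, with the description left as unknown for each of the 15208 probes. The reference table of the assembly fPimPro1.hap1.1 lists 64593 genes, and 0 of the 15208 probe or contig names matched it. No probe was therefore given a gene name. The lists of liver pathways, estrogen-responsive genes and cell type markers fixed before the data were examined held 0 matched probes, so no list was tested. The planned rule named the highest and lowest fold changes among named genes past the threshold. Without gene names, the 2 highest and 2 lowest probes by the same ranking are given.

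The labels also hold 9 measures per fish, among them weights, steroid levels and the liver mRNA of vitellogenin (vtg) and estrogen receptor 1 (esr1). The series' design text places the gonad sampling and the QPCR with males, while the labels give these values for the arrayed females. The values were used as the labels give them, and this was not resolved. The units of both mRNA measures and of plasma vitellogenin (VTG) are not stated in the labels. Each measure was tested with Spearman's rho against dose rank by 100000 permutations in Python with numpy 2.4.6, adjusted over the 9 measures. Each dose was also set against control by an exact permutation test, for which 3 fish against 3 cannot give a two-sided p under 0.1. Spike-in variation and slope were copied from the file headers.

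The arrays lay on 3 slides, and the scan date went with the slide, so the scan date gave no alternative of its own. Slide 1 held 5 arrays from all 4 groups, slide 2 held 3 arrays without a 100 ng/L fish, and slide 3 held 4 arrays from all 4 groups. Alternatives chosen before the data were examined were other normalizations, background corrections and filters, blocks for tank number, title number and slide, the gonadosomatic index as a covariate, array weights, 2 groups only, and leaving out each fish. The pipeline was tested on simulated arrays with 12233 probes, a few of them changed. For 100 ng/L against control it called 0 of 67 probes changed 2-fold, 9 of 67 changed 4-fold and 42 of 66 changed 8-fold, with 1 false call. For 10 ng/L against control it called 1 of 67, 10 of 67 and 40 of 66, with 3 false calls. With so few probes changed, 4-fold changes thus mostly go uncalled.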

Results

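Female fathead minnows, a small North American fish used in endocrine testing, were exposed for 96 h to 0, 1, 10 or 100 ng/L DES, and the liver transcriptome of 3 fish per group was measured. The question stated by the series is the estrogenic potency of DES in this species. The 12 fish were separate animals from 3 tanks per treatment. Between 8120 and 13415 of the 15208 probes (53.4% to 88.2%) were well above background on each array. The 75th percentile of the processed signal ran from 45.2 to 278.5. The control arrays were the dimmest, with a mean log2 75th percentile of 5.88 ± 0.55 (SD, n = 3), when compared to 7.23 ± 0.48 at 1 ng/L, 7.57 ± 0.40 at 10 ng/L and 7.71 ± 0.40 at 100 ng/L (n = 3 each).

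The labels of the arrayed females give vitellogenin, steroid and gonad measures, although the series' design text places the gonad sampling and QPCR with males, so whether every value comes from the same females is uncertain. Vitellogenin, the egg yolk precursor that the liver makes in response to estrogen, was higher at 10 and 100 ng/L than in control fish, both as liver mRNA and as plasma protein. Liver vtg mRNA averaged 8.63e+05 ± 7.47e+05 label units in control fish (SD, n = 3) and 6.44e+06 ± 7.37e+05 at 100 ng/L (n = 3), a ratio of means of 7.47. The ratio was 14.0 without control replicate 3 and 5.39 to 7.96 without any other fish of these groups. At 10 ng/L it averaged 2.77e+06 ± 5.37e+05 (n = 3), and all 3 fish lay above every control fish. Plasma VTG averaged 6.03 ± 4.65 label units in control fish, 8.5 ± 5.76 at 1 ng/L, 32.6 ± 13.4 at 10 ng/L and 46.3 ± 15.9 at 100 ng/L (SD, n = 3 each). The ratio of its means at 100 ng/L to control was 7.68. It was 13.6 without control replicate 3 and 5.94 to 9.1 without any other fish of these groups. Plasma VTG had a rho with dose rank of 0.86 over the 12 fish (permutation test, two-sided p = 0.0008, adjusted p = 0.0056 over 9 measures). Liver vtg mRNA had a rho of 0.84 (permutation p = 0.0012, adjusted p = 0.0056). All 3 fish at 10 ng/L and all 3 at 100 ng/L had more plasma VTG than every control fish. For both vitellogenin measures, the exact permutation test of either of these doses against control gave p = 0.1, the smallest that 3 fish against 3 allow.

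At 1 ng/L, the mean vitellogenin measures differed from control by less than the spread between fish. In liver vtg mRNA, 2 of the 3 fish lay above every control fish and 1 lay below every control fish. Liver vtg mRNA there averaged 1.99e+06 ± 2.07e+06 (n = 3, exact permutation p = 0.6), and the exact p for plasma VTG was 0.8. DES 1 ng/L replicate 5 had a liver vtg mRNA of 358 label units, while the lowest value in any other fish was 1.97e+05. That fish also had the lowest plasma VTG (2.01) and the lowest esr1 mRNA (62.7) of the 12.

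Liver esr1 mRNA, which encodes an estrogen receptor, averaged 105 ± 25.6 label units in control fish, 183 ± 105 at 1 ng/L, 125 ± 20.4 at 10 ng/L and 142 ± 9.62 at 100 ng/L (n = 3 each). All 3 fish at 100 ng/L lay above every control fish (exact permutation p = 0.1), but rho with dose rank was 0.35 (permutation p = 0.28, adjusted p = 0.42). Ex vivo estradiol (E2) production averaged 0.271 ± 0.1 ng/ml/12 h in control fish and 0.0532 ± 0.0801 at 100 ng/L (n = 3 each), where all 3 fish lay below every control fish (exact permutation p = 0.1). Its rho with dose rank was -0.54 (permutation p = 0.079, adjusted p = 0.18). Wet weight gave a rho of -0.59 (p = 0.047, adjusted p = 0.14), and without control replicate 1 it was -0.72 (adjusted p = 0.049). The gonadosomatic index averaged 4.0% ± 1.28 in control fish, 8.43% ± 5.29 at 1 ng/L, 3.55% ± 0.547 at 10 ng/L and 9.19% ± 2.15 at 100 ng/L (n = 3 each), with a rho of 0.37 (adjusted p = 0.42). Gonad weight, ex vivo testosterone and plasma E2 gave rho values of 0.22, -0.23 and -0.28, with adjusted p of 0.52, 0.52 and 0.5.

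**Figure D1:**
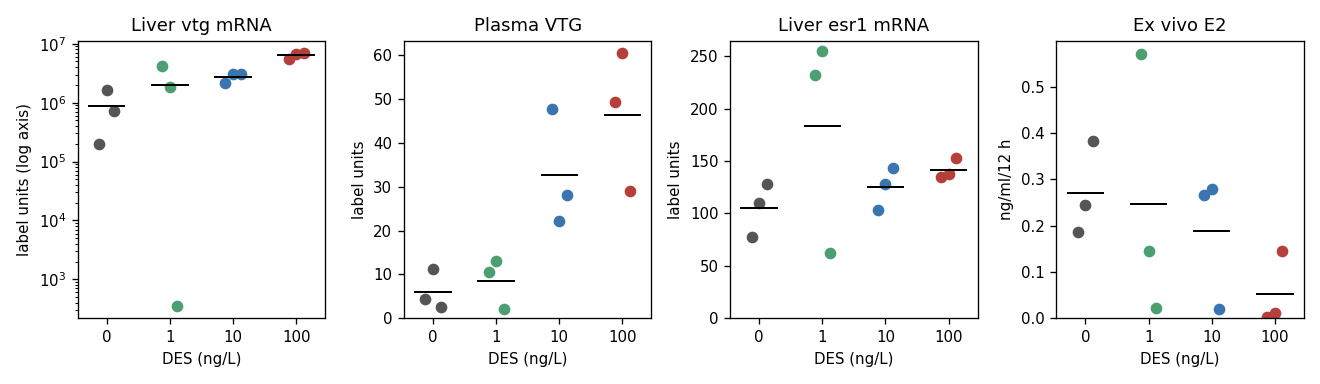
Each point is one fish (3 per dose) and each line the group mean, for liver vtg mRNA (label units, log axis), plasma VTG (label units), liver esr1 mRNA (label units) and ex vivo E2 (ng/ml/12 h) against DES in ng/L. The 3 fish at 100 ng/L have the highest liver vtg mRNA, from 5.59e+06 to 6.91e+06.

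At 100 ng/L DES, 2998 of the 12233 tested probes (24.5%) differed from control at an adjusted p under 0.05 in limma. Of these, 1441 were higher and 1557 lower. The median log2 fold change was 2.18 among the higher probes (quartiles 1.71 and 2.82) and -2.16 among the lower ones (quartiles -2.85 and -1.68). A change of over 2 on the log2 scale was seen in 859 of the higher and 904 of the lower probes. Of the higher probes, 453 were not well above background on any control array. Of the lower probes, 296 were not well above background on any 100 ng/L array. For these the fitted fold is set by the floor of the array. The 100 ng/L arrays also had a steeper spike-in slope (1.08 ± 0.0557, SD, n = 3) than the other groups (means of 0.862 to 0.884), so the calls at 100 ng/L go with a technical difference between the arrays.

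Probe UF_Ppr_AF_101723 (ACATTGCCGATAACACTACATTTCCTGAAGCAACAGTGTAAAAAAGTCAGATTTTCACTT) had the highest fitted fold change at 100 ng/L. Its normalized log2 signal was 4.25 ± 2.90 in control fish and 12.53 ± 0.06 at 100 ng/L (SD, n = 3 each), a log2 fold change of 8.28 ± 1.34 (SE, adjusted p = 0.0033). The group means at 1 and 10 ng/L were 8.67 ± 2.33 and 10.47 ± 0.95, with adjusted p of 0.23 and 0.16 against control. It was well above background in 1 of the 3 control fish and in all 9 exposed fish, so the fitted fold rests in part on the floor of the control arrays. It was 4.92 with the normexp background correction, 6.88 without control replicate 6 and 9.79 without control replicate 3. Probe UF_Ppr_AF_119087 (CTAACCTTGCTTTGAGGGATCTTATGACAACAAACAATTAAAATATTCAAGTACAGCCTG) was not well above background in any control fish. At 100 ng/L it was at least 74.8-fold higher (n = 3 each), a bound set against the lowest signal well above background on each control array. The adjusted p of 0.007 in limma belongs to the fitted log2 fold change of 8 ± 1.64 (SE), which rests on control values at the floor. Its log2 signal at 100 ng/L was 10.14 ± 4.48, with 1 fish at 5.03 and the others at 12.02 and 13.37. At 1 ng/L it was well above background in all 3 fish, at 3.38, 5.99 and 4.28, a range that holds the 100 ng/L fish at 5.03. At 10 ng/L it was not well above background in any fish, so its signal did not follow the order of the doses. The difference between 100 and 10 ng/L had an adjusted p of 0.055. The bound was 24.4-fold without DES 100 ng/L replicate 2, 39.0-fold without DES 100 ng/L replicate 3 and 439-fold without DES 100 ng/L replicate 6. With the normexp background correction the call was lost (adjusted p = 0.14, fitted log2 fold change 2.44).

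Probe UF_Ppr_AF_118577 (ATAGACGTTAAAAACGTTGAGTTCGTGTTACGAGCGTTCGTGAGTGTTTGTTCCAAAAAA) fell by 7.87 ± 1.43 on the log2 scale at 100 ng/L (SE, n = 3 each, adjusted p = 0.0047). Its mean was 16.14 ± 0.44 in control fish, 15.20 ± 0.80 at 1 ng/L, 15.29 ± 0.51 at 10 ng/L and 8.27 ± 3.98 at 100 ng/L (SD), where the 3 fish stood at 12.84, 5.60 and 6.37. The spot was saturated in 1 fish at 1 ng/L and in 1 at 10 ng/L, so those means include capped values. The log2 fold change was -10.11 without DES 100 ng/L replicate 2, -6.38 without DES 100 ng/L replicate 3 and -5.54 with the normexp background correction. Its adjusted p against control was 0.77 at 1 ng/L and 0.8 at 10 ng/L, and between 100 and 10 ng/L it was 0.063. Probe UF_Ppr_AF_101517 (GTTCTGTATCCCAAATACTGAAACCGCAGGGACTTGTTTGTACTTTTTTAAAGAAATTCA) fell by 7.86 ± 2.05 (SE, n = 3 each, adjusted p = 0.019), from 12.00 ± 1.23 in control fish to 4.15 ± 3.50 at 100 ng/L (SD). It was well above background in 2 of the 3 fish at 100 ng/L. Leaving out 1 fish moved its log2 fold change between -9.80 and -6.49. Its call was lost under 6 of 17 alternative settings, with a fold of -7.34 without control replicate 3, -7.32 and -6.49 without DES 100 ng/L replicates 2 and 6, -6.35 with the gonadosomatic index, -4.59 with normexp and -3.86 with the authors' value table.

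**Figure D2:**
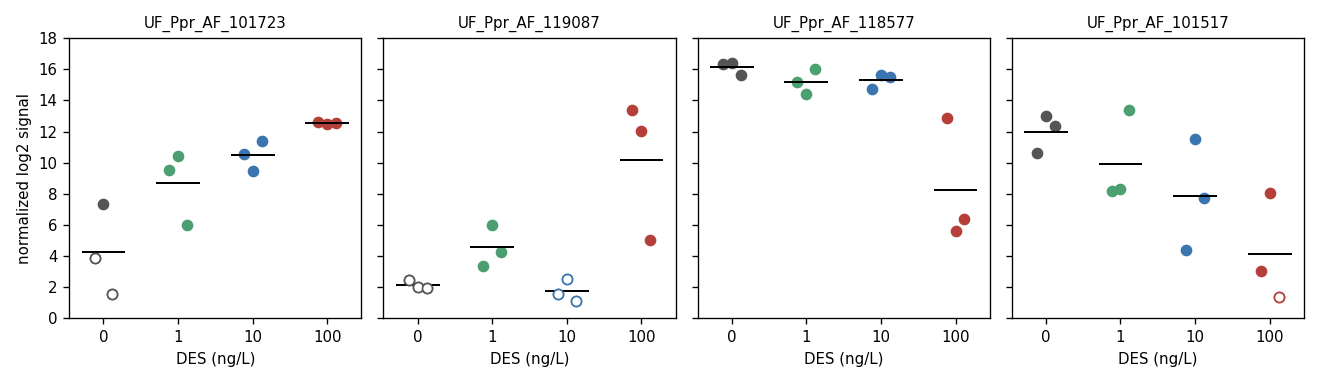
Normalized log2 signal of the 2 probes with the highest and the 2 with the lowest fold change at 100 ng/L, against DES in ng/L. Each point is one fish (3 per dose), open points were not well above background, and lines are group means. UF_Ppr_AF_101723 averages 4.25 in control fish and 12.53 at 100 ng/L.

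The count of 2998 probes depended on single fish and on the processing. It was 1530 without control replicate 1, whose label notes that the fish was immature, 1824 without DES 100 ng/L replicate 2 and 1883 without DES 100 ng/L replicate 6. It was 322 with a normexp background correction, 5201 with the authors' value table, 1200 with the gonadosomatic index as a covariate, 1819 without 3 arrays with high spike-in variation and 0 with array brightness as a covariate, the last 2 settings chosen after the data were seen. With slide as a block it was 2289. Slide 2 held no fish at 100 ng/L. The fold changes within slide 1 (3 arrays) and within slide 3 (2 arrays), which share no array, correlated across all tested probes with r = 0.69, though probes are not independent replicates. On both slides the control array was dimmer and had a lower spike-in slope than the 100 ng/L arrays. An array effect could therefore give such a correlation too. With each array scaled by its 75th percentile instead, 1055 probes were higher and 1941 lower (35.2% higher, against 48.1%). That scaling moved the median of all tested probes at 100 ng/L to -0.36, from 0.05 under cyclic loess. With the authors' value table, normalized within dose groups, 5056 probes were higher and 145 lower (97.2% higher). The near-even split thus depends on the normalization.

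At 1 and 10 ng/L, 0 of the 12233 probes differed from control in limma. The smallest adjusted p was 0.11 at 1 ng/L and 0.074 at 10 ng/L. At an unadjusted p under 0.05 there were 1856 probes at 1 ng/L and 2036 at 10 ng/L, when 612 are expected by chance alone. These unadjusted counts fell to 189 and 108 with array brightness as a covariate, a setting chosen after the data were seen. Leaving out single fish moved the unadjusted counts both ways. At 1 ng/L they were 1107 without DES 1 ng/L replicate 1, 1225 without control replicate 1 and 2432 without DES 1 ng/L replicate 5. At 10 ng/L they were 1120 without DES 10 ng/L replicate 1, 1272 without control replicate 1 and 2195 without control replicate 6. With the authors' value table the counts were 4204 at 1 ng/L, of which 4202 were higher, and 5438 at 10 ng/L, of which 5433 were higher. Without DES 1 ng/L replicate 5, 5 probes passed at 10 ng/L. With slide as a block, 0 probes passed at either dose. Fold changes within slides correlated with r of 0.26, 0.25 and -0.15 between pairs of slides at 1 ng/L, and with 0.18, 0.38 and 0.09 at 10 ng/L.

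A linear trend over dose rank passed in 2762 probes, 1353 rising and 1409 falling, with median slopes of 0.70 and -0.68 (log2) per dose step. Of these, 2629 were also called at 100 ng/L against control in the same direction. The trend gives its largest weights to the same control and 100 ng/L arrays, so this overlap is largely built in. Between 10 and 1 ng/L, a contrast that uses neither control nor 100 ng/L arrays, 71.5% of the 1441 probes higher at 100 ng/L against control were higher at 10 ng/L, against 49.9% of all tested probes. Of the 1557 lower probes, 50.5% were lower at 10 ng/L, against 50.1% of all. Fold changes between 10 and 1 ng/L within slides correlated with r of -0.47, 0.26 and -0.24 between pairs of slides. This contrast thus did not repeat between slides, and the 71.5% does not establish a rise from 1 to 10 ng/L. The 10 ng/L arrays were also brighter on average (mean log2 75th percentile 7.57 against 7.23). The median log2 fold change of the 1557 lower probes against control was -1.11 at 1 ng/L and -1.08 at 10 ng/L. In the higher probes it was 0.84 and 1.1. A call at 100 ng/L against control thus need not mean a change at every dose step. The dose steps of the trend probes were not counted on their own, though 2629 of the 2762 are among these calls. The trend count was 1395 without control replicate 1, 1643 without DES 100 ng/L replicate 2 and 1705 without DES 100 ng/L replicate 6. It was 2121 with slide as a block and, scaled by the 75th percentile, 1012 rose and 1819 fell. It was 310 with the normexp background correction, 5201 with the authors' value table (5104 rising, 97 falling), 1738 without the 3 arrays with high spike-in variation, and 0 with array brightness as a covariate.

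**Figure D3:**
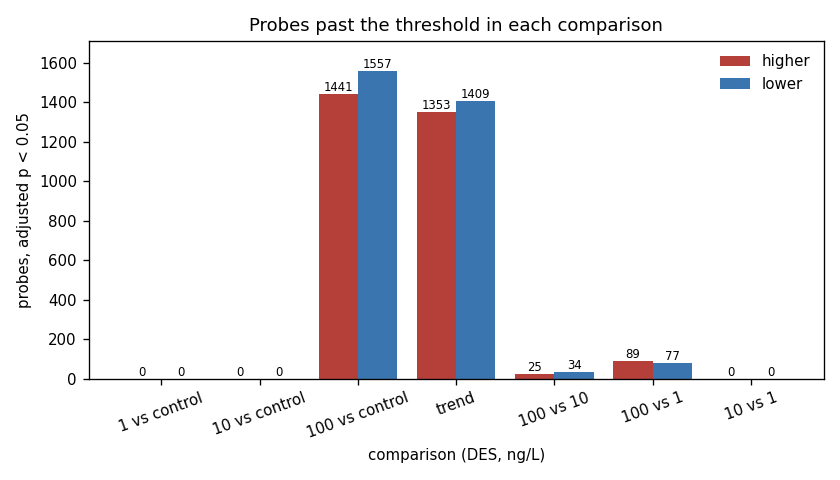
Bars give the number of probes with adjusted p under 0.05 in each comparison, higher or lower in the first named dose (rising or falling for the trend). The 100 ng/L group gives 1441 higher and 1557 lower probes, and no probe passes at 1 or 10 ng/L.

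Setting doses against each other, 59 probes differed between 100 and 10 ng/L (25 higher, 34 lower at 100 ng/L), 166 between 100 and 1 ng/L (89 higher, 77 lower) and 0 between 10 and 1 ng/L in limma, where 278 had an unadjusted p under 0.05. The 278 became 142 and 155 without DES 10 ng/L replicates 1 and 5. It became 555 without DES 1 ng/L replicate 2 and 846 without DES 10 ng/L replicate 2, when 612 are expected by chance alone. Of the 59, 58 were also called at 100 ng/L against control in the same direction, and 157 of the 166 were. These comparisons use the same 100 ng/L arrays, so the overlap is in part built in. With slide as a block, 7 and 29 probes passed. The 59 became 36 without control replicate 6, 12, 19 and 8 without DES 10 ng/L replicates 1, 2 and 5, and 31 without DES 100 ng/L replicate 2 or replicate 6. The 166 became 92 without control replicate 6, 20 without DES 1 ng/L replicate 5, 66 without DES 10 ng/L replicate 5, and 47, 71 and 51 without DES 100 ng/L replicates 2, 3 and 6. With the normexp background correction they became 0 and 4.

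Across the tested probes, fold changes against the shared control correlated with r = 0.77 between 1 and 10 ng/L, 0.74 between 1 and 100 ng/L and 0.78 between 10 and 100 ng/L. Simulated unchanged groups, each set against a shared simulated control, gave 0.5 for each pair. With equal noise and equal group sizes this value is fixed in advance, and the real control arrays did not enter it. It therefore cannot separate a shared response to DES from a shared departure of the control arrays. The simulation held no link between exposed fish of the same tank number, whose deviations from the group means correlated with r of 0.04 to 0.48, so this may be part of the excess too. The covariances were 0.674, 1.05 and 1.11, when compared to simulated values of 0.214, 0.215 and 0.214. With 0 probes called at 1 and 10 ng/L, no probe was called at 2 doses and 0 were expected. The 3 control arrays are too few to split, so part of the excess in correlation may come from the shared controls, and the dimmer control arrays enter all 3 contrasts alike.

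The first principal component held 35.1% of the variance. On it the control fish lay between -106.5 and -65.3, the fish at 1 ng/L between -51.5 and 26.2, those at 10 ng/L between -19.1 and 14.4, and those at 100 ng/L between 78.1 and 89.9. DES 1 ng/L replicate 5, the fish with the low liver vtg mRNA, lay closest to the control fish. Its array was also the dimmest exposed one, with a log2 75th percentile of 6.862 when compared to 6.515 for control replicate 6, the brightest control array. The control arrays were the dimmest of all, so dose and array brightness cannot be told apart on this component. The second component (16.5%) set DES 1 ng/L replicate 1, DES 10 ng/L replicate 2 and DES 100 ng/L replicate 3 on 1 side, at -84.7, -48.5 and -49.4, and DES 100 ng/L replicate 2 and DES 10 ng/L replicate 1 farthest on the other, at 70.4 and 54.7. The first 3 named are the arrays with high spike-in variation.

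**Figure D4:**
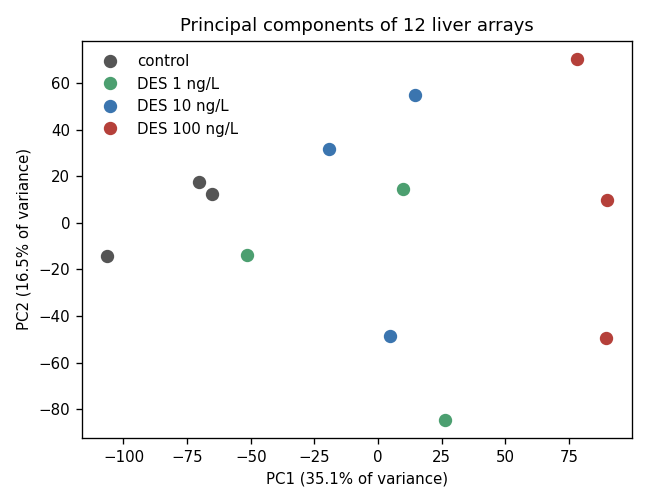
Each point is the liver array of one fish on the first (35.1% of variance) and second (16.5%) principal component of the normalized log2 signals, coloured by dose group. The 3 control fish lie lowest and the 3 fish at 100 ng/L highest on the first component, and the control arrays were also the dimmest.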

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

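The tests of array brightness were chosen after the result was seen. The fit with the gonadosomatic index as a covariate was planned, but its use as a test of the whole cause was set after the result was seen. The tests of neighbouring spots and of regrouped arrays were fixed before their results.

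The spike-in RNA added to every labelling reaction varied more on 3 arrays than on any control array. Its median coefficient of variation was 16.4% for DES 1 ng/L replicate 1, 8.72% for DES 10 ng/L replicate 2 and 5.80% for DES 100 ng/L replicate 3, when compared to 3.76% on the highest control array. All 3 fish came from tank number 2 of their dose, and their deviations from the group means correlated with r of 0.44 to 0.48, but control replicate 3, also from a tank numbered 2, correlated with them at 0.03, 0.02 and -0.11. Uneven hybridization is one possible explanation. Neighbouring spots deviated together with r of 0.119, 0.091 and 0.081 on these arrays, while the highest of the other 9 arrays gave 0.13. This neither supports uneven hybridization nor rules it out, and tank and array preparation cannot be told apart for 3 arrays. DES 1 ng/L replicate 1 and DES 10 ng/L replicate 2 also had 13415 and 13060 probes well above background. Their log2 25th percentiles of processed signal were 4.508 and 4.516. DES 100 ng/L replicate 3 had 10295 and 3.068, and the highest of the other 9 arrays had 9866 and 3.088.

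The 2998 probes called at 100 ng/L stand beside control arrays that were the dimmest, by 1.35, 1.69 and 1.83 (log2) when compared to 1, 10 and 100 ng/L. Dimmer control arrays as the whole cause are argued against by the 10 ng/L arrays, which were nearly as bright. Probes called without one 100 ng/L fish lay beyond the 10 ng/L mean in that left-out fish by a median of 0.88 to 1.09 (log2). This does not speak to other array effects: the 100 ng/L arrays also had a steeper spike-in slope (1.08 ± 0.0557, SD, n = 3) than the 10 ng/L arrays (0.884 ± 0.0274, n = 3), and whether they were labelled apart is not stated. Slide and scan do not go with the slope: on slide 1 it was 1.016 and 1.107 for the 100 ng/L arrays and 0.879 to 0.916 for the other 3. Other sources of the slope were not tested and stay open, as slope and dose go together. A part played by brightness stays open. Set directly against the nearly as bright 10 ng/L arrays, the 100 ng/L arrays differed in 59 probes (0.482%), when compared to 24.5% called against control. Across settings the 59 ran from 0 with normexp to 645 with array weights. How many of the 2998 calls brightness accounts for is therefore not known. With brightness as a covariate, the median fold change of the called probes went from 2.17 to 1.38, its median standard error from 0.52 to 1.01, and the count to 0. The call ended because the fold shrank and the error grew, as brightness and the control group go together. With the gonadosomatic index as a covariate there were 1200 calls, 1044 of them shared with the 2998, and a median fold change of 2.03 (standard error 0.64). This cannot exclude the index as the whole cause. All 3 fish at 100 ng/L had a higher index than every control fish. The fitted slope comes from differences within groups, which were widest at 1 ng/L (SD 5.29, n = 3). Whether the index values belong to the arrayed females is also uncertain. An effect of DES itself remains among the open explanations.

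With 10 splits of 6 arrays, no share under 0.05 is possible. The real count was 2998 and the highest other 0 at 100 ng/L, with 1 of 10 splits as large. It was 59 and 0 for 100 against 10 ng/L (1 of 10), 166 and 1 for 100 against 1 ng/L (1 of 10), 0 and 3 at 1 ng/L (10 of 10), 0 and 0 at 10 ng/L (10 of 10), and 0 and 0 for 10 against 1 ng/L (10 of 10). For the dose trend, 1 of 100 regroupings of the 12 arrays, the real one with 2762 probes, gave as many, and the highest other gave 53. This argues against a random assignment of arrays to groups as the source of that count. The regroupings treated the arrays as exchangeable, although tank number and slide link some of them. They cannot tell dose from array brightness or spike-in slope. The trend also gives its largest weights to the control and 100 ng/L arrays, as does the comparison at 100 ng/L.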

How the results depend on the processing

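The authors' table normalized again, array brightness, normexp with offset 1, leaving out 3 arrays and contig averages were chosen only after results were seen. The other settings were fixed before.

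At 100 ng/L the 2998 probes became 322 with normexp (offset 50), 243 with offset 1, 5201 with the authors' value table, 1200 with the gonadosomatic index, 1819 without the 3 arrays with high spike-in variation and 0 (578 nominal) with array brightness in limma. Leaving out 1 fish gave 1530 to 3123. The trend's 2762 became 310, 223, 5201, 1705, 1738 and 0 (498 nominal) under the same settings, and 1395 to 2810 without 1 fish.

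At 1 ng/L the 0 became 4204 with the authors' value table, 1 with that table normalized again over 12 arrays and 1 with probes well above background on all 12 arrays. At 10 ng/L these gave 5438, 1 and 1. Leaving out 1 fish gave 0 to 0 at 1 ng/L and 0 to 5 at 10 ng/L. The table was normalized within dose groups, so its group means carry array brightness. Between 10 and 1 ng/L every setting gave 0 (0 to 0 without 1 fish).

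Between 100 and 10 ng/L the 59 became 0 (683 nominal) with normexp (offset 50), 0 (437 nominal) with offset 1, 359 with the authors' value table, 332 with it normalized again, 118 with probes above background on all 12 arrays, 7 with slide as a block, 20 with the gonadosomatic index, 645 with array weights, 13 with 2 groups only, 35 with brightness and 2 without the 3 arrays. Leaving out 1 fish gave 8 to 84.

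Between 100 and 1 ng/L the 166 became 47 with the 75th percentile, 76 with quantile normalization, 4 and 2 with normexp (offsets 50 and 1), 1582 and 695 with the authors' value table as given and normalized again, 419 with probes above background on all 12 arrays, 29 with slide, 21 with 2 groups only, 20 with brightness and 48 without the 3 arrays. Leaving out 1 fish gave 20 to 192.

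With tank number as a replicate block, 99 probes differed between 100 and 10 ng/L. With title number as a replicate block in 4 arrays, 0 (3093 nominal) passed at 100 ng/L. The title numbers do not pair the samples (r of -0.11 and 0.03). Permuting within tank (replicate block), rho stayed 0.86 for plasma VTG (adjusted p 0.011) and 0.84 for liver vtg mRNA (adjusted p 0.011), the 2 measures that passed. Leaving out 1 fish, rho for plasma VTG ran from 0.83 to 0.92, and for liver vtg mRNA from 0.80 to 0.90. The measures passing ran from 2 to 3, wet weight being the added one (without control replicate 1).

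Gene lists, array against QPCR and averages over genes were not run, as 0 probes were named.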

Other observations

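The 15 or more shared bases test below was fixed before its result, and the other values here were looked at only after the data were seen.

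Across the 12 fish, liver vtg mRNA and plasma VTG (both log10) correlated with r = 0.75 (permutation p = 0.00044, adjusted p = 0.0013 over 3 relations) and rho = 0.80 (permutation p = 0.0026, adjusted p = 0.0049). Without the 2 fish farthest from the median of liver vtg mRNA, DES 1 ng/L replicate 5 and control replicate 1, r was 0.78 over 10 fish (permutation p = 0.0085). Both rise with dose, and 3 fish per dose are too few for a value within a dose. Liver vtg and esr1 mRNA gave r = 0.69 (permutation p = 0.0059, adjusted p = 0.0059) and rho = 0.66 (permutation p = 0.023, adjusted p = 0.023), but without the same 2 fish r was 0.15 (permutation p = 0.68), so this relation rests on them.

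Of 12233 probes, 1 followed liver vtg mRNA over the 12 fish at an adjusted p under 0.05 in limma. It was UF_Ppr_AF_117573 (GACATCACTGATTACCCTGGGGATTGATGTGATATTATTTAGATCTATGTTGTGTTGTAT), chosen after its values were seen, with an adjusted p of 0.003, r = 0.96 (permutation p = 0.0014) and rho = 0.78 (permutation p = 0.0033). Its log2 signal was 7.83 in DES 1 ng/L replicate 5 and 11.79 to 13.75 in the other 11 fish. Without the 2 fish farthest from the median, r was 0.41 (permutation p = 0.24), so this relation rests on them too. With dose group in the model, 0 probes followed liver vtg mRNA (1258 with an unadjusted p under 0.05). With plasma VTG, 857 probes were associated, and 0 once dose group was in the model, where 977 had an unadjusted p under 0.05.

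Probe UF_Ppr_AF_102486 had the widest fitted range over the 12 fish (13.24 on the log2 scale) and was not called at any dose. The lower end of this range is set by the floor of the array, as the probe was not well above background in its lowest fish. It stood at 15.66 in control replicate 3, 11.92 in DES 1 ng/L replicate 5 and 10.71 in DES 100 ng/L replicate 2, and at 2.42 to 8.02 in the other 9 fish. In all, 59 probes with a range over 5, itself included, shared its deviations from the group means with r over 0.9. Their median log2 signal was 9.79, 7.12 and 6.83 in those 3 fish and 1.36 to 3.60 in the others. The 59 were picked by this likeness on the same arrays, so a high signal in the same 3 fish is largely built in. Of the 59, 2 were called at 100 ng/L, and their wide spread within groups makes a call less likely. The files do not name these probes, and no source of the shared signal was tested.

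The spike-in series, whose input is the same for every array, had a fitted slope of 1.08 ± 0.0557 on the 100 ng/L arrays (SD, n = 3), when compared to 0.874 ± 0.0238 in control, 0.862 ± 0.0274 at 1 ng/L and 0.884 ± 0.0274 at 10 ng/L (n = 3 each). This goes with the dose of the 2998, 59 and 166 calls. Slide and scan did not go with the slope, and no other explanation was tested.

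Fold changes of probes of the same contig correlated weakly. Of 709 contigs with 2 probes, 393 had both tested, and the log2 fold changes of both probes at 100 ng/L correlated with r = 0.10 across contigs, which are not independent replicates. Both probes were called for 35 contigs, in the same direction for 28, and 1 of the 2 was called for 149. Where 1 or both were called, 61.4% of pairs moved in the same direction. A candidate explanation is that probes that move apart read opposite strands. Of the 709 pairs, 9 shared 15 or more bases as reverse complements and 0 shared them in the same orientation, while 700 shared none. The 9 pairs fit such a design, and the 7 tested among them had fold changes that correlated with r = 0.37, too few pairs to tell this from the 0.10 over all pairs. The 9 are also too few for the limit of 10 pairs set beforehand, and the other pairs share no sequence that would tell. Some probe names carry the suffixes rc or _ms, whose meaning is not stated, and these were not used. The mean signals of the 2 probes of a contig correlated with r = -0.02. The 2 probes thus did not follow each other in level either, and whether they read the same transcript is open.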
